A study of Chelonia mydas with 15 samples.

How the data were processed

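The series holds RNA sequencing of 15 embryo samples of Chelonia mydas in 3 groups of 5: freshly laid, 36 h in normoxia and 36 h in hypoxia. Per the labels' protocols, freshly laid embryos were taken within 1 h of laying, normoxia eggs were kept in sand, and hypoxia eggs were kept in sand in bags filled with nitrogen, at 26 to 28 °C, and total RNA was extracted from frozen embryos. The labels do not state the female or clutch of an egg. Details of library preparation are not given in the sources used here.

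The deposited values are raw counts per gene and library. Reads were mapped with STAR and counted with featureCounts, per the submitters' processing notes, which give no versions. The counts come from featureCounts 1.6.2 with strand setting 2 and a mapping quality of at least 10, per the file headers, over the exons of the annotation of the assembly rCheMyd1.pri. Duplicate reads were marked and still counted, per the file headers. The notes also name limma. Of the count columns, 3 match no listed sample and were not used here. One further entry carries no gene name and lies on the mitochondrial sequence. It stayed out of library totals and tests, and held 0.114 ± 0.0780% of the counts in freshly laid embryos, 0.142 ± 0.0555% in normoxia and 0.230 ± 0.106% in hypoxia (SD, n = 5 each). Of the 23730 named genes, 8844 carry a locus number as their name. Genes encoded by the mitochondrial genome were not analysed here.

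Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, libraries scaled with TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 15 libraries, with 12 residual degrees of freedom. Each of the 3 group comparisons used the quasi-likelihood F test with p adjusted by Benjamini and Hochberg, and a gene is called when its adjusted p is under 0.05. CPM are the counts of a gene relative to the library total after TMM scaling, and ± is the SD between the 5 libraries of a group. Fold values come from the model, so they can differ slightly from the ratio of mean CPM. Where a group had no count for a gene, the fold is given as a lower limit over 3 counts for the group, and where it had 1 to 3 counts, as a ratio of summed counts with a 95% interval.

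Before the data were examined, 34 gene lists with 934 members were fixed, of which 829 members were found in the file. Lists with at least 5 tested members were tested with camera from limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and p adjusted over the lists of each comparison, and the adjusted p with an estimated correlation is given beside it. Beside the genes called over all tested genes, the number called when p is adjusted over the list alone is given. The comparisons, tests, thresholds, lists, naming rule and most alternatives were also fixed before the data were examined.

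Genes named in each comparison follow a rule fixed at the same time. They are the 10 largest rises and the 10 largest falls among called genes with a gene symbol, a mean of at least 20 counts in the higher group and no overlap between the groups in CPM, up to 4 tested members of each list with the smallest adjusted p, and 12 fixed genes: TBXT, EOMES, NODAL, VEGFA, EGLN3, SLC2A1, PDK1, LDHA, HIF1A, CDKN1A, CCNB1 and MCM2. The rule lets lists that are only counted go without examples. Of the genes it names among the list examples, 2 are not reported here. Which lists are described with examples was chosen after the values were seen.

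Both 36 h groups share the freshly laid libraries. The overlap of their calls was compared with independent lists, with 20 simulations of unchanged groups against the shared libraries and with 20 splits of the freshly laid libraries into 2 and 3. Depth ran from 14.5 to 26.8 M counts per library, and the common biological coefficient of variation was 0.367. The edgeR and camera steps were tested on simulated counts with 200 genes changed by known amounts. For normoxia against freshly laid (16438 genes run), 65.3% and 86.0% of genes changed by -2 and 2 on the log2 scale were recovered, and 44.0% and 46.0% of those changed by -1 and 1. For hypoxia against freshly laid (16424 genes) the shares were 70.0%, 74.0%, 47.9% and 54.0%, and for hypoxia against normoxia (16399 genes) 72.0%, 70.0%, 45.8% and 32.7%. Unchanged genes made up 2.94%, 6.25% and 3.20% of the called genes, and 0 of 20 unchanged lists were called in each comparison while the raised list was called. Few genes were changed around a common mean, so the simulated groups hardly differed in composition. In the real comparisons 31.2%, 40.3% and 48.8% of genes were called. The simulated error rates therefore do not cover the scaling differences seen in hypoxia. The simulated genes were drawn independently of each other. The list result therefore does not cover lists whose genes vary together, and the estimated correlation of the ribosomal protein list in the real data was 0.637.

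Alternatives were median-ratio and total-count scaling, no filter and a filter of CPM above 1 in at least 5 libraries, the Wald test of DESeq2 1.42.0, limma-voom without and with quality weights, fits on 10 libraries, an adjusted p under 0.01, a test against a fold of 2, an estimated correlation and leaving out each library. Added after the data were seen were a covariate for the block of index numbers in the column names, summing of normoxia pairs with neighbouring sample numbers, a block for 5 sets of sample numbers, and leaving out each library for the list counts and the overlap. Unusual libraries were searched with Dixon's test at a limit of 0.71 for 5 libraries.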

Results

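Gene expression was measured by RNA sequencing in 15 embryo libraries of the green sea turtle, Chelonia mydas, a reptile whose embryos stop developing inside the oviduct and resume after the egg is laid. The 5 freshly laid libraries came from embryos taken out within 1 h of laying. The 5 normoxia libraries came from eggs kept for 36 h in sand at an oxygen tension of about 159 mmHg, and the 5 hypoxia libraries from eggs kept for 36 h in nitrogen-filled bags below 8 mmHg. Library totals ran from 14.5 to 21.8 M counts in freshly laid embryos, from 18.3 to 26.8 M in normoxia and from 17.6 to 20.8 M in hypoxia. Of 23730 named genes, 16639 had enough counts to be tested. The labels name each library as its own sample without saying which female or clutch it came from, so the p-values measure only the spread between these samples.

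The first principal component of log2 CPM, the library-scaled counts of a gene, held 33.5% of the variance and set the hypoxia libraries apart from the normoxia libraries, with the freshly laid libraries between them. The second held 23.4% and set the freshly laid libraries apart from both 36 h groups. The 10 most counted genes took 6.32 ± 0.560% of the counts in freshly laid embryos, 4.63 ± 0.399% in normoxia and 9.55 ± 1.09% in hypoxia (SD, n = 5 each). The scaling factors for library composition lay between 0.785 and 0.904 in hypoxia and between 1.00 and 1.14 in the other 2 groups. Scaling by total counts alone moved the median log2 fold change of all genes by -0.31 for hypoxia against freshly laid and by -0.32 for hypoxia against normoxia, so changes in hypoxia are reported relative to the composition scaling.

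**Figure D1:**
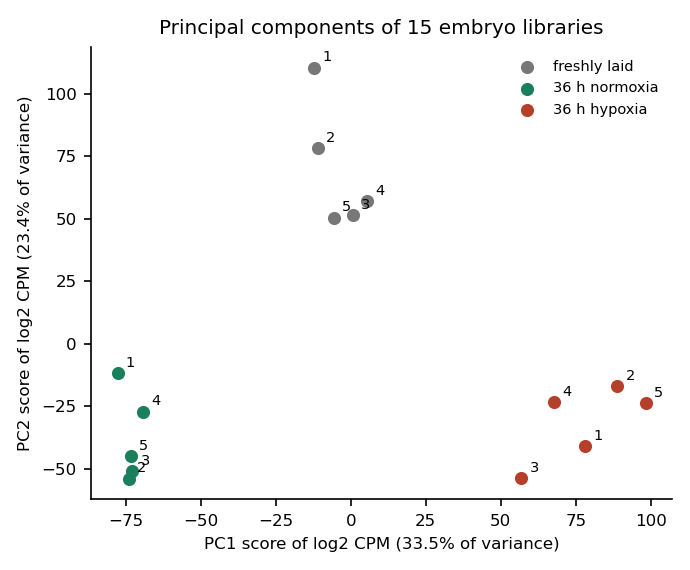
Scores of the 15 embryo libraries on the first principal component (horizontal axis, 33.5% of the variance of log2 CPM) and the second (vertical axis, 23.4%); each point is 1 library, coloured by group and numbered by replicate. The 3 groups of 5 libraries occupy separate areas, and freshly laid replicate 1 has the highest score on the second component.

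The comparison of normoxia with freshly laid embryos asks what changes during the first 36 h in air. Higher in normoxia were 12 of 18 genes of presomitic mesoderm and somites, 13 of 26 of the neural plate and neurons, 12 of 23 of the neural border and crest and 13 of 18 of yolk tissue, and lower were 6 of 15 pluripotency genes, 14 of 31 targets of the hypoxia-inducible factors and 12 of 19 of glycolysis. All 7 lists passed the camera test with a preset correlation between genes, and none did with an estimated correlation (adjusted p 0.187 to 0.317). MSGN1, a transcription factor of presomitic mesoderm, had no count in the 5 freshly laid libraries and 19.5 ± 11.1 CPM in normoxia (SD, n = 5), at least 622-fold higher over a floor of 3 counts for the group. Floors and counting intervals cover the counting error only. PRDM14, a regulator of pluripotency and germ cell fate, fell from 96.2 ± 21.7 to 3.81 ± 1.94 CPM. EGLN3, a prolyl hydroxylase that marks hypoxia-inducible factors for degradation and is itself one of their targets, fell from 85.4 ± 20.1 to 13.7 ± 2.82 CPM. Of the 16639 genes tested with edgeR's quasi-likelihood test, 5193 passed an adjusted p of 0.05, 2521 of them higher and 2672 lower in normoxia.

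Of 18 tested genes of presomitic mesoderm and somites, 12 rose and 6 were not called (13 rose when adjusted over the list alone). The camera test of this list gave an adjusted p = 5.14e-06, and an adjusted p = 0.187 with an estimated correlation. Besides MSGN1, the forkhead factor FOXC2 rose from 0.0547 to 4.85 CPM, the segmentation gene RIPPLY1 from 0.442 to 18.9 CPM and the Notch ligand DLL1 from 18.6 to 115 CPM. The list of neural border and crest had 12 genes higher, 2 lower and 9 not called among 23 (12 higher and 3 lower adjusted over the list alone). The border and crest list had a camera adjusted p = 0.000481, and an adjusted p = 0.187 with an estimated correlation. TWIST1, a mesenchymal and neural crest factor, rose from 0.0469 to 6.71 CPM, EYA2 rose 3.45-fold, and ZIC1 had no count in freshly laid embryos and 3.91 CPM in normoxia, at least 121-fold higher. Among 26 genes of the neural plate and neurons, 13 rose, 2 fell and 11 were not called (13 higher and 3 lower adjusted over the list alone). The neural list had a camera adjusted p = 0.0013, and an adjusted p = 0.276 with an estimated correlation. IRX1 rose 32.4-fold and OTX1 7.66-fold, NKX2-2 went from no count to 1.26 CPM, at least 39.9-fold higher, and SOX3, expressed in epiblast and early neural tissue, fell from 153 to 56.4 CPM. Of 39 HOX genes, which set position along the body axis, only 11 had enough counts to be tested. In freshly laid embryos 0 of these 11 had a mean above 10 CPM, so they had little room to fall. The same limit held for many members of other developmental lists. Above 10 CPM were 4 of 18 somite, 4 of 26 neural, 6 of 23 border and crest, 7 of 20 heart and 7 of 18 yolk genes. By contrast, all 35 replication and all 34 oxidative phosphorylation genes were. Of the 11 HOX genes, 7 rose and 4 were not called (9 rose when adjusted over the list alone). The HOX list had a camera adjusted p = 0.000143, and an adjusted p = 0.189 with an estimated correlation. HOXA3 rose 10.6-fold, HOXB3 39.4-fold, HOXD1 4.91-fold and HOXA7 from 0.169 to 1.73 CPM.

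In the list of pluripotency and epiblast genes, 6 of 15 fell, 1 rose and 8 were not called (7 lower and 1 higher adjusted over the list alone). The pluripotency list had a camera adjusted p = 0.00193, and an adjusted p = 0.189 with an estimated correlation. Together with PRDM14, the pluripotency factor POU5F1 fell 14.1-fold, to 3.63 ± 2.12 CPM, the DNA methyltransferase DNMT3B from 1450.3 to 368 CPM and KLF5 from 161 to 61.1 CPM. Genes of gastrulation and the primitive streak moved both ways: 5 of 26 rose, 7 fell and 14 were not called (6 and 7 adjusted over the list alone), the list was not called (camera adjusted p = 0.728), and its median (0.07) and mean (-0.26) log2 fold change differed in sign. FOXH1, a partner of Nodal signalling, fell 12.3-fold, the mesendoderm factor MIXL1 from 81.6 to 15.1 CPM, the secreted signal NODAL from 8.63 ± 5.75 to 0.0897 ± 0.0858 CPM, and EOMES from 86.4 ± 50.7 to 28.1 ± 15.3 CPM. The caudal factors CDX2 and CDX4 rose 6.88-fold and 5.24-fold. TBXT, the Brachyury gene of the streak and notochord, had 36.7 ± 28.3 CPM in freshly laid embryos and 60.2 ± 10.4 CPM in normoxia and was not called (edgeR adjusted p = 0.257). It was called with limma-voom (limma adjusted p = 0.0353), and without freshly laid replicate 1 its log2 fold change was 1.28 with an edgeR adjusted p = 0.0373.

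Among 31 tested targets of hypoxia-inducible factors, 14 fell, 2 rose and 15 were not called (14 lower and 3 higher adjusted over the list alone). The list of these targets had a camera adjusted p = 0.00012, and an adjusted p = 0.187 with an estimated correlation. Besides EGLN3, the histone demethylase KDM3A fell from 177 to 50.1 CPM, the glucose transporter SLC2A1 from 671 ± 102 to 159 ± 33.2 CPM, and DDIT4, an inhibitor of mTOR signalling, fell 5.37-fold. The growth factor VEGFA (10.4 ± 3.31 and 11.9 ± 1.77 CPM) and the kinase PDK1 (11.5 and 10.8 CPM) were not called. Their edgeR adjusted p were 0.501 and 0.896. HIF1A, the oxygen-regulated factor itself, had 119 and 155 CPM and was not called (edgeR adjusted p = 0.189), although its log2 fold change was 0.59 with an edgeR adjusted p = 0.0345 without freshly laid replicate 3. Of 19 glycolysis genes, 12 fell and 7 were not called (13 fell when adjusted over the list alone). The glycolysis list had a camera adjusted p = 7.67e-07, and an adjusted p = 0.187 with an estimated correlation. The hexokinase HK1 fell 4.18-fold, LDHA, which reduces pyruvate to lactate, from 733 ± 121 to 188 ± 49.5 CPM, the pyruvate kinase PKM from 6050.2 to 1574 CPM and the enolase ENO1 from 10858 to 3130.4 CPM. Nuclear genes of oxidative phosphorylation moved the other way, with 24 of 34 higher and 10 not called (25 higher and 1 lower adjusted over the list alone). The oxidative phosphorylation list had a camera adjusted p = 7.07e-08, and an adjusted p = 0.276 with an estimated correlation. The complex I subunits NDUFA5, NDUFA8 and NDUFB10 rose 2.40-fold, 2.08-fold and 1.98-fold, and the ATP synthase subunit ATP5PB rose 1.83-fold.

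Markers of extraembryonic yolk tissue, which the dissected embryos could carry, rose with the developmental groups: 13 of 18 were higher, 1 lower and 4 not called (13 and 1 adjusted over the list alone). The yolk list had a camera adjusted p = 0.000673, and an adjusted p = 0.317 with an estimated correlation. The trophoblast and epithelial factor GATA3 rose 5.07-fold, the fibrinogen chain FGA from 0.659 ± 0.587 to 62.9 ± 72.4 CPM, and the fatty acid binding protein FABP2 from no count to 2.07 CPM, at least 64.4-fold higher. CDX2 belonged to this list as well. Further genes with the largest rises were the bile salt transporter subunit SLC51B, 775-fold higher by total counts (95% counting interval 139 to 30644), and the coagulation factor F7 (642-fold, 115 to 25405). Also among them were SPP2 (571-fold, 158 to 4717), SKOR1 (143-fold, 39.2 to 1182) and the keratin KRT23, with no count in freshly laid embryos and at least 63.4-fold higher in normoxia. The largest falls besides NODAL and PRDM14 were in LRRC74A (95.9-fold by total counts, interval 26.1 to 799), RGS18 (51.3-fold), FBXO40 (33.0-fold), the lymphocyte adaptor SH2D1A (31.6-fold) and the T-box factor TBX21 (28.7-fold). Further falls were in NEU2 (19.1-fold), SERTM1 (18.9-fold) and SEPTIN3 (18.1-fold). Without freshly laid replicate 3, the log2 fold change of SERTM1 was -3.26 instead of -4.24 and that of LRRC74A -5.57 instead of -6.22, and without normoxia replicate 2 that of FGA was 5.62 instead of 6.58, all still called. Leaving out 1 library made other folds larger: TWIST1 and RIPPLY1 without freshly laid replicate 5 (8.34 and 6.09 instead of 6.83 and 5.36), HOXB3 without freshly laid replicate 4 (6.13 instead of 5.30), HOXA7 without freshly laid replicate 1 (4.18 instead of 3.33), SLC51B and F7 without freshly laid replicate 3 (10.35 and 10.06 instead of 8.89 and 8.60), FGA without freshly laid replicate 2 (7.18), RGS18 and FBXO40 without normoxia replicate 4 (-6.51 and -5.66 instead of -5.68 and -5.04), FBXO40 and NODAL without normoxia replicate 5 (-5.70, and -7.22 instead of -6.54) and LRRC74A without normoxia replicate 2 (-8.03). The cell cycle genes fixed beforehand were not called: CDKN1A, an inhibitor of cyclin-dependent kinases, had 5.46 and 9.43 CPM, the mitotic cyclin CCNB1 108 and 150 CPM and the replicative helicase subunit MCM2 165 and 200 CPM, with edgeR adjusted p of 0.0823, 0.199 and 0.347. CDKN1A was called with DESeq2 (DESeq2 adjusted p = 0.0471), and CCNB1 when only the 10 libraries of both groups were fitted (edgeR adjusted p = 0.0199).

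Lists that passed the camera test upwards with fewer members called were DNA replication (13 of 35 higher, adjusted over the list alone 16 higher and 1 lower; camera adjusted p = 0.000175, adjusted p = 0.296 with an estimated correlation), the tricarboxylic acid cycle (8 of 20, 8 over the list alone, 0.00211 and 0.296), growth arrest (8 of 19, 8, 0.00601 and 0.187) and heart and lateral mesoderm (5 of 20, 3, 0.0103 and 0.396). In the same order of values, heat shock proteins had 10 of 21 higher and 2 lower (10 and 2 over the list alone; camera adjusted p = 0.00828, and 0.296 with an estimated correlation). Antioxidant defence had 8 and 1 of 27 (8 and 1, 0.00718 and 0.246), and blood and endothelium 3 and 1 of 23 (3 and 1, 0.0157 and 0.586). The amino acid and unfolded protein responses had 12 and 2 of 28 (12 and 2, 0.0429 and 0.656) and ribosome biogenesis 8 and 2 of 30 (9 and 2, 0.0451 and 0.598). Only 2 of 47 ribosomal protein genes were higher, and 0 when adjusted over the list alone, although the list passed camera (adjusted p = 0.00394, and adjusted p = 0.656 with an estimated correlation). Oxygen-dependent chromatin demethylases had 10 of 18 lower and 1 higher (12 and 2 over the list alone; camera adjusted p = 0.00425, and adjusted p = 0.187 with an estimated correlation). The insulin and growth factor axis had 9 of 17 lower and 2 higher (9 and 2). The insulin list had a camera adjusted p = 0.0361, and an adjusted p = 0.187 with an estimated correlation. Not called were oxygen sensing (4 higher and 3 lower of 13, median 0.23 and mean -0.03), mitosis (4 and 1 of 31), mTOR signalling and autophagy (3 and 5 of 29) and apoptosis (1 and 4 of 17). Neither were cholesterol synthesis (1 and 1 of 20), immediate early genes (3 higher of 16), signalling feedback targets (9 and 5 of 27), endoderm and gut (5 and 1 of 15), extracellular matrix (4 and 7 of 30), oocyte and germline (3 and 1 of 13) and leukocytes (3 and 1 of 14). Summing the pairs of normoxia libraries with neighbouring sample numbers, a setting chosen after seeing the data, left 2987 called genes and ended the calls of EOMES (edgeR adjusted p = 0.0658), HOXA7 (0.0761) and HOXD1 (0.0513), and the call of EOMES also ended with the index number block as a covariate (0.0585). The 21 called lists became 0 with an estimated correlation.

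**Figure D2:**
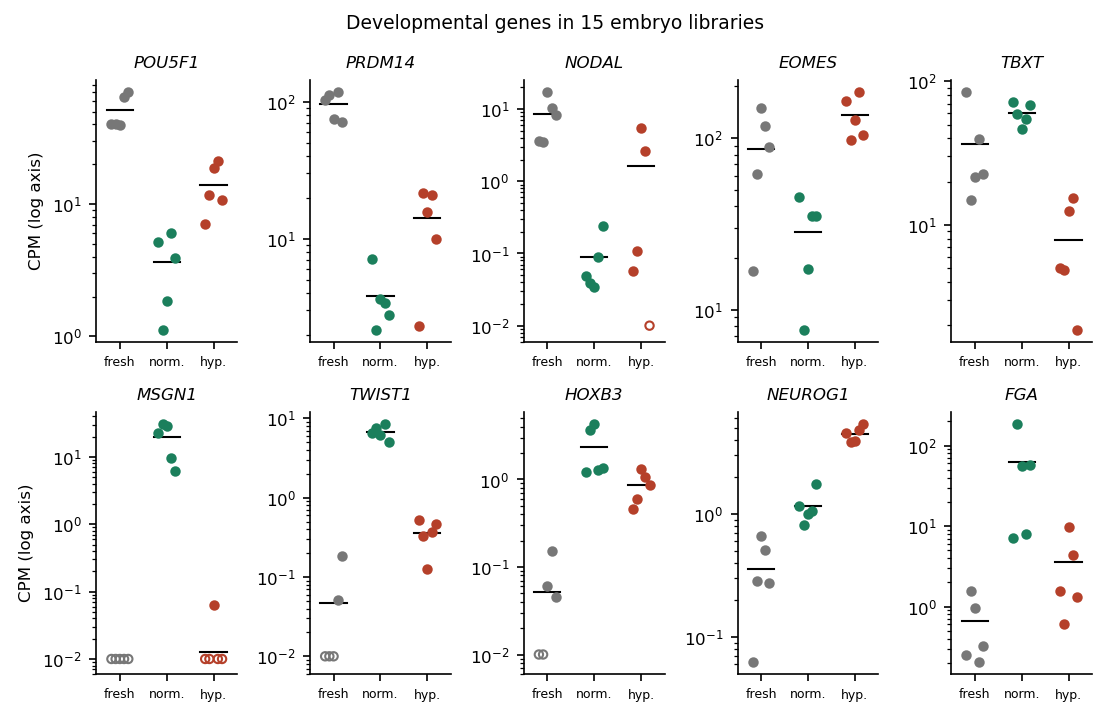
CPM of 10 developmental genes (log vertical axis) in the freshly laid, normoxia and hypoxia libraries, 5 per group; points are libraries, open circles at the bottom are libraries with no count, and bars are group means. POU5F1 falls from 51.0 to 3.63 CPM in normoxia, MSGN1 has counts in all 5 normoxia libraries and in 1 hypoxia library, and NEUROG1 is highest in hypoxia at 4.50 CPM.

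The comparison of hypoxia with freshly laid embryos asks what changes over 36 h at low oxygen after laying. Higher in hypoxia were 26 of 31 targets of hypoxia-inducible factors, all 28 genes of the amino acid and unfolded protein responses and all 47 ribosomal protein genes, and lower were 28 of 35 genes of DNA replication and all 31 of mitosis. All 5 lists passed camera with the preset correlation, and those of ribosomal proteins (adjusted p = 0.355) and mitosis (adjusted p = 0.119) did not with an estimated correlation. ATF3, a stress-induced transcription factor, rose from 0.601 ± 0.232 to 101 ± 24.4 CPM (SD, n = 5 each). LDHA rose from 733 ± 121 to 5643 ± 1578 CPM, and MCM2 fell from 165 ± 46.0 to 22.4 ± 6.85 CPM. With edgeR, 6701 of 16639 genes passed an adjusted p of 0.05, 3474 higher and 3227 lower in hypoxia; scaled by total counts alone, 2088 were higher and 5259 lower.

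Of 31 targets of hypoxia-inducible factors, 26 rose and 5 were not called (27 higher and 2 lower adjusted over the list alone). The list of these targets had a camera adjusted p = 7e-16, and an adjusted p = 0.0228 with an estimated correlation. The secreted glycoprotein gene STC2 rose 40.9-fold, EGLN3 8.50-fold, the lysyl oxidase LOX 9.81-fold, the transcriptional repressor MXI1 4.62-fold and VEGFA 5.96-fold. SLC2A1 (671 and 483 CPM), PDK1 (11.5 and 9.86 CPM) and HIF1A (119 and 98.6 CPM) were not called. Their edgeR adjusted p were 0.06, 0.734 and 0.34. SLC2A1 was called lower with total counts only (edgeR adjusted p = 0.00345), with DESeq2 (0.0451), with limma-voom (0.046) and with the index number block as a covariate (0.0422), and HIF1A with total counts only (edgeR adjusted p = 0.0463). Among 19 glycolysis genes 11 rose, 3 fell and 5 were not called (11 and 3 adjusted over the list alone). The glycolysis list had a camera adjusted p = 0.00218, and an adjusted p = 0.378 with an estimated correlation. LDHA rose 7.70-fold, ENO2 7.13-fold, the glucose phosphate isomerase GPI 2.88-fold and GAPDH 2.65-fold. All 28 tested genes of the amino acid and unfolded protein responses rose, also adjusted over the list alone and under total-count scaling (camera adjusted p = 1.51e-23, and adjusted p = 0.0456 with an estimated correlation). CHAC1, which degrades glutathione, rose 18.8-fold, the chaperone DNAJB9 from 11.8 to 130 CPM, the transcription factor XBP1 7.33-fold and the amino acid transporter subunit SLC3A2 6.35-fold. Immediate early genes had 11 of 16 higher, 2 lower and 3 not called (12 and 2 adjusted over the list alone; camera adjusted p = 1.28e-05, and adjusted p = 0.0456 with an estimated correlation). JUNB was 6.25-fold, FOSL2 6.44-fold and the mRNA decay factor ZFP36 7.78-fold higher beside ATF3. Of 18 oxygen-dependent chromatin demethylases, 14 rose and 4 were not called (14 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.28e-05, and adjusted p = 0.0228 with an estimated correlation). TET3 rose 7.46-fold, TET2 9.86-fold, KDM3A 4.15-fold and KDM4B from 68.7 to 261 CPM.

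Genes of DNA replication fell in 28 of 35 cases, with 7 not called (30 lower adjusted over the list alone). The replication list had a camera adjusted p = 5.17e-15, and an adjusted p = 0.0456 with an estimated correlation. MCM2 fell 7.35-fold, the cyclin CCNE2 6.68-fold, UHRF1, which maintains DNA methylation, 3.87-fold and MCM10 3.74-fold. All 31 tested genes of mitosis fell, also adjusted over the list alone (camera adjusted p = 2.03e-19, and adjusted p = 0.119 with an estimated correlation). KIF23, a kinesin of cytokinesis, fell 4.40-fold, CCNB2 3.91-fold, the kinetochore gene NUF2 2.87-fold and CCNB1 3.12-fold, and CDCA8 fell from 261 to 49.3 CPM. Of 19 genes of growth arrest and p53 targets, 12 rose and 7 were not called (12 higher and 2 lower adjusted over the list alone). The growth arrest list had a camera adjusted p = 0.000118, and an adjusted p = 0.0456 with an estimated correlation. CDKN1A rose 19.8-fold, GADD45B 5.07-fold, CDKN1B 3.54-fold and CCNG1 2.59-fold. All 47 ribosomal protein genes rose, also adjusted over the list alone, and 26 of them under total-count scaling (camera adjusted p = 2.17e-15, and adjusted p = 0.355 with an estimated correlation). RPL3 rose 1.89-fold, RPS20 1.90-fold and RPS18 1.85-fold. Heat shock proteins moved both ways, with 3 of 21 higher, 11 lower and 7 not called (4 and 11 adjusted over the list alone). The heat shock list had a camera adjusted p = 0.0218, and an adjusted p = 0.405 with an estimated correlation. The co-chaperones and chaperones AHSA1, HSPA4L and HSPH1 fell 4.35-fold, 10.3-fold and 5.10-fold, and HSPA2 rose 7.15-fold.

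In the list of pluripotency genes 3 of 15 fell and 12 were not called, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0904). PRDM14 fell 6.83-fold, POU5F1 3.68-fold and DNMT3B 2.90-fold, and SOX3 (153 and 105 CPM) was not called (edgeR adjusted p = 0.0759). It was called lower without hypoxia replicate 3 (edgeR adjusted p = 0.0459), with total counts only (0.00971) and with the index number block (0.0375). Of 26 genes of the neural plate and neurons, 11 rose, 1 fell and 14 were not called (12 and 1 adjusted over the list alone). The neural list had a camera adjusted p = 0.00691, and an adjusted p = 0.378 with an estimated correlation. The proneural factor NEUROG1 rose 12.3-fold, NKX6-1 14.2-fold, IRX1 12.4-fold and IRX3 6.15-fold. Among the 18 yolk tissue markers 12 rose and 6 were not called (13 rose when adjusted over the list alone). The yolk list had a camera adjusted p = 0.00378, and an adjusted p = 0.439 with an estimated correlation. GATA3 rose 5.10-fold, the keratins KRT18 and KRT8 3.92-fold and 2.67-fold, and the apolipoprotein APOA1 from 13.8 ± 7.51 to 185 ± 163 CPM. TBXT fell 4.64-fold, while EOMES (86.4 and 136 CPM) and NODAL (8.63 ± 5.75 and 1.65 ± 2.41 CPM) were not called. Their edgeR adjusted p were 0.275 and 0.0545; without hypoxia replicate 3 the log2 fold change of NODAL was -3.63 with an edgeR adjusted p = 0.00779. NODAL was also called lower with limma-voom (limma adjusted p = 0.00277), with total counts only (edgeR adjusted p = 0.0353) and with the index number block (0.0439).

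The largest rises besides ATF3 were in ATOH1, a proneural factor with no count in freshly laid embryos and at least 81.7-fold higher in hypoxia, HES3 (285-fold by total counts, interval 78.5 to 2358), SLC51B (246-fold, 43.7 to 9768), SKOR1 (56.3-fold, 15.2 to 471) and C10H15orf48 (79.8-fold). The same rule named ABCB5 (45.3-fold), INA (45.0-fold), SLC17A9 (from 0.0632 to 3.12 CPM) and the melanocortin receptor MC5R (from 0.0665 to 4.45 CPM, where hypoxia replicate 1 had 19.5 CPM and the other 4 libraries 0.331 to 1.14 CPM). The largest falls were in SOST (41.0-fold), SEPTIN3 (28.7-fold) and MMD2 (16.4-fold). Next came CALB1 (13.9-fold), LRRC27 (12.5-fold), LRRN2 (11.7-fold), MYBL1 (11.7-fold), the phosphate transporter SLC34A2 (11.3-fold), KCNU1 (11.2-fold) and TNFAIP6 (10.7-fold). Leaving out 1 library moved some log2 fold changes towards 0: MC5R without hypoxia replicate 1 (3.29 instead of 5.94), APOA1 and SLC51B without hypoxia replicate 3 (3.12 and 6.55 instead of 3.74 and 7.29), SLC17A9 without hypoxia replicate 5 (4.84 instead of 5.45) and TNFAIP6 without freshly laid replicate 3 (-2.82 instead of -3.42). It made others larger: INA without freshly laid replicate 2 (7.38 instead of 5.49), SLC51B without freshly laid replicate 3 (8.75), ABCB5 and SLC17A9 without freshly laid replicate 4 (6.27 instead of 5.50, and 7.25), HES3 without freshly laid replicate 5 (9.91 instead of 7.81), MMD2 without hypoxia replicate 1 (-4.65 instead of -4.03), and CALB1 and TNFAIP6 without hypoxia replicate 3 (-4.63 instead of -3.80, and -4.33). All these calls stayed. Endoderm and gut genes had 7 of 15 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.00247, and adjusted p = 0.378 with an estimated correlation). The insulin and growth factor axis had 9 of 17 higher and 3 lower (9 and 3). The insulin list had a camera adjusted p = 0.0222, and an adjusted p = 0.0782 with an estimated correlation. Not called were oxygen sensing (4 higher and 2 lower of 13), the tricarboxylic acid cycle (7 and 4 of 20, median below 0 and mean 0.14), oxidative phosphorylation (10 and 3 of 34, but 3 and 12 under total-count scaling), antioxidant defence (9 and 5 of 27), mTOR signalling and autophagy (10 and 5 of 29), apoptosis (4 and 2 of 17, median -0.03 and mean 0.10), ribosome biogenesis (7 and 13 of 30) and cholesterol synthesis (2 and 2 of 20). Under total-count scaling the medians of oxygen sensing, oxidative phosphorylation, mTOR signalling and cholesterol synthesis turned negative. Also not called were signalling feedback targets (4 and 3 of 27), gastrulation (2 and 5 of 26), somites (5 higher of 18), heart mesoderm (3 higher of 20), blood and endothelium (6 and 2 of 23), neural border and crest (4 and 1 of 23), HOX genes (2 higher of 11), extracellular matrix (11 and 4 of 30), oocyte and germline (4 and 1 of 13, median -0.01 and mean 0.36) and leukocytes (2 and 1 of 14). Under total-count scaling the medians of signalling feedback targets and leukocytes turned negative. Among the genes named here as called, CALB1 lost its call with limma-voom (limma adjusted p = 0.0816). The 14 called lists became 6 with an estimated correlation.

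**Figure D3:**
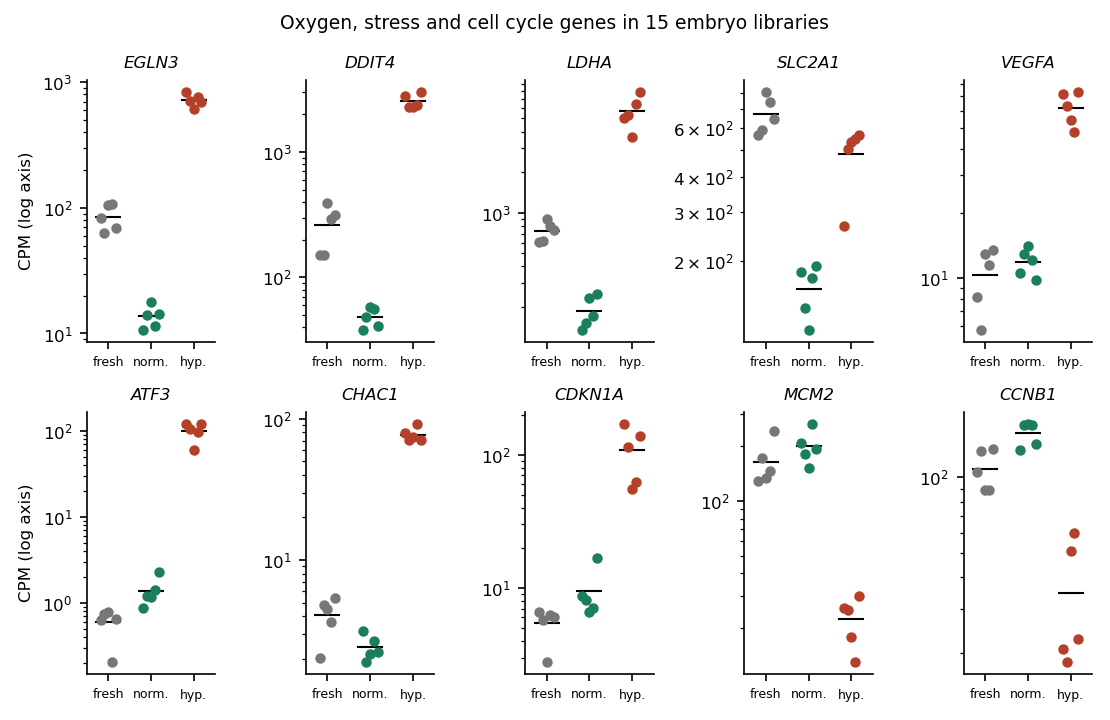
CPM of 10 genes of oxygen response, stress and cell cycle (log vertical axis) in the freshly laid, normoxia and hypoxia libraries, 5 per group; points are libraries and bars are group means. EGLN3 lies at 13.7 CPM in normoxia, 85.4 CPM in freshly laid embryos and 726 CPM in hypoxia, and MCM2 is lowest in hypoxia at 22.4 CPM.

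The comparison of both 36 h groups asks which differences go with oxygen at the same time after laying. Higher in hypoxia than in normoxia were 26 of 31 targets of hypoxia-inducible factors, 16 of 19 glycolysis genes and 26 of 28 genes of the amino acid and unfolded protein responses, and lower were 33 of 35 genes of DNA replication, all 31 of mitosis, 19 of 34 of oxidative phosphorylation (4 were higher) and 8 of 18 of somites. With an estimated correlation the camera calls of the hypoxia-inducible factor and replication lists stayed (adjusted p 0.00836 and 0.0481), and those of glycolysis, the amino acid response, mitosis, oxidative phosphorylation and somites did not (adjusted p 0.101, 0.101, 0.172, 0.571 and 0.36). EGLN3 had 13.7 ± 2.82 CPM in normoxia and 726 ± 82.7 CPM in hypoxia, a 53.1-fold difference (SD, n = 5 each). RRM2, a ribonucleotide reductase subunit, fell from 258 ± 66.6 to 14.4 ± 6.59 CPM, and RIPPLY1 from 18.9 ± 8.93 to 0.386 ± 0.247 CPM. With edgeR, 8123 of 16639 genes passed an adjusted p of 0.05, 4268 higher and 3855 lower in hypoxia; scaled by total counts alone, 2674 were higher and 5600 lower.

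Of the 31 targets of hypoxia-inducible factors, 26 were higher, 1 lower and 4 not called (26 and 1 adjusted over the list alone). The list of these targets had a camera adjusted p = 4e-16, and an adjusted p = 0.00836 with an estimated correlation. DDIT4 was 52.8-fold higher, KDM3A 14.7-fold, MXI1 8.32-fold, VEGFA 5.19-fold and SLC2A1 3.03-fold, and PDK1 (10.8 and 9.86 CPM) was not called (edgeR adjusted p = 0.839). HIF1A fell from 155 to 98.6 CPM with an edgeR adjusted p = 0.0194, and this call was lost without normoxia replicate 1 (edgeR adjusted p = 0.0504), without hypoxia replicate 2 (0.0547) and with the index number block as a covariate (0.0503). Among 19 glycolysis genes 16 rose and 3 were not called, also adjusted over the list alone (camera adjusted p = 2.23e-08, and adjusted p = 0.101 with an estimated correlation). HK1 was 11.1-fold higher, LDHA rose from 188 to 5643 CPM, GPI from 415 to 1907 CPM and ENO2 from 5.62 to 84.1 CPM. Of 34 oxidative phosphorylation genes 19 fell, 4 rose and 11 were not called, also adjusted over the list alone (camera adjusted p = 0.000729, and adjusted p = 0.571 with an estimated correlation). The ATP synthase subunit ATP5MC3 fell 5.05-fold, NDUFB10 2.62-fold, NDUFA5 2.08-fold and NDUFV2 1.93-fold. The amino acid and unfolded protein responses had 26 of 28 genes higher and 2 not called, also adjusted over the list alone (camera adjusted p = 9.05e-16, and adjusted p = 0.101 with an estimated correlation), with CHAC1 31.9-fold, DDIT4 52.8-fold, the mitochondrial folate enzyme MTHFD2 14.4-fold and CEBPG 4.70-fold higher. Oxygen-dependent chromatin demethylases had 13 of 18 higher, 1 lower and 4 not called, also adjusted over the list alone (camera adjusted p = 3.7e-07, and adjusted p = 0.00836 with an estimated correlation). KDM4B was 8.31-fold higher, KDM6B 7.02-fold and TET3 5.66-fold. In the insulin and growth factor axis 8 of 17 rose and 9 were not called, also adjusted over the list alone (camera adjusted p = 0.000421, and adjusted p = 0.0139 with an estimated correlation). The binding proteins IGFBP3 and IGFBP1 rose from 3.98 to 65.2 CPM and from 5.28 to 66.9 CPM, IRS4 2.67-fold and the RNA-binding protein gene IGF2BP2 1.64-fold.

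DNA replication genes were lower in 33 of 35 cases and not called in 2, also adjusted over the list alone (camera adjusted p = 2.56e-16, and adjusted p = 0.0481 with an estimated correlation). Besides RRM2, CCNE2 fell 13.6-fold, the replication factor CDC45 7.48-fold, UHRF1 5.82-fold and MCM2 8.93-fold. All 31 genes of mitosis fell, also adjusted over the list alone (camera adjusted p = 2.56e-16, and adjusted p = 0.172 with an estimated correlation), among them KIF23 (6.92-fold), CCNB2 (5.23-fold), NUF2 (3.27-fold), CCNB1 (4.33-fold) and the kinetochore gene NDC80 (from 68.2 to 22.1 CPM), while CDKN1A rose 11.5-fold. Heat shock proteins had 12 of 21 lower, 5 higher and 4 not called (13 and 6 adjusted over the list alone). The heat shock list had a camera adjusted p = 0.00616, and an adjusted p = 0.36 with an estimated correlation. HSPA4L fell 19.4-fold, HSPH1 11.5-fold, AHSA1 7.84-fold and DNAJA1 3.61-fold. Of 18 genes of presomitic mesoderm and somites 8 fell and 10 were not called, also adjusted over the list alone (camera adjusted p = 0.00773, and adjusted p = 0.36 with an estimated correlation). MSGN1 had 1 count over the 5 hypoxia libraries and 2433 over the 5 normoxia libraries, a ratio of 1689 with a 95% counting interval of 303 to 66753. RIPPLY1 fell 47.6-fold, FOXC2 15.2-fold and ALDH1A2, which makes retinoic acid, 3.27-fold. The list of neural plate and neurons was not called (camera adjusted p = 0.815): 4 of 26 genes rose, 6 fell and 16 were not called, also adjusted over the list alone. DLX2 rose 4.88-fold, the eye field factor RAX 27.4-fold, NEUROG1 3.87-fold and SOX3 from 56.4 to 105 CPM. TBXT fell from 60.2 to 7.90 CPM and EOMES rose 4.83-fold. NODAL rose from 0.0897 to 1.65 ± 2.41 CPM (edgeR adjusted p = 0.00707), a call that ended with limma-voom (limma adjusted p = 0.312) and with the index number block (edgeR adjusted p = 0.0548). Without hypoxia replicate 3 the log2 fold change of NODAL was 2.91 instead of 4.16 (edgeR adjusted p = 0.0349), and without normoxia replicate 5 it was 4.83.

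The largest rises besides EGLN3 and DDIT4 were in C10H15orf48 (134-fold), ANKRD37 (93.5-fold), FBXO40 (81.6-fold) and STC2 (64.9-fold). Also among them were AK5 (51.7-fold), ZAR1, known from oocytes (43.4-fold), DSCAM (49.4-fold by total counts, interval 16.5 to 244) and ATF3 (from 1.39 to 101 CPM). The largest falls besides MSGN1 were in ATP12A and the trophoblast and glial factor GCM1, which had no count in hypoxia and were at least 102-fold and 25.0-fold lower, ZNF750 (206-fold by total counts, interval 36.7 to 8172), and ATP6V1G3 (140-fold, 24.9 to 5567). Lower as well were KRT23 (86.1-fold, 23.6 to 715), CLDN2 (75.7-fold, 13.3 to 3016), SPP2 (80.1-fold), the kinase SGK1 (55.0-fold) and COL13A1 (from 5.79 to 0.111 CPM). Leaving out 1 library made these log2 fold changes larger: MSGN1, ZNF750, CLDN2, SPP2 and COL13A1 without hypoxia replicate 3 (-11.60, -8.63, -7.20, -8.41 and -6.45 instead of -10.04, -7.08, -5.65, -6.32 and -5.64), ATP6V1G3 without hypoxia replicate 2 (-8.04 instead of -6.52), KRT23 without hypoxia replicate 4 (-8.30 instead of -6.02), C10H15orf48 and DSCAM without normoxia replicate 3 (7.77 and 6.14 instead of 7.07 and 5.34), and FBXO40 without normoxia replicate 4 or 5 (at least 6.96 instead of 6.35). Ribosomal protein genes had 30 of 47 higher and 17 not called (32 higher adjusted over the list alone, and 7 higher under total-count scaling). The ribosomal protein list had a camera adjusted p = 5.27e-07, and an adjusted p = 0.553 with an estimated correlation. Immediate early genes had 11 of 16 higher and 2 lower (12 and 2 adjusted over the list alone; camera adjusted p = 0.000729, and adjusted p = 0.126 with an estimated correlation). Ribosome biogenesis had 16 of 30 lower and 7 higher, also adjusted over the list alone (camera adjusted p = 0.0234, and adjusted p = 0.584 with an estimated correlation). Of 11 HOX genes 3 were lower (1 adjusted over the list alone; camera adjusted p = 0.0497, and adjusted p = 0.553 with an estimated correlation), a call that ended under median-ratio scaling (camera adjusted p = 0.0534). Not called were oxygen sensing (3 higher and 4 lower of 13, median -0.35 and mean 0.37), the tricarboxylic acid cycle (4 and 8 of 20), growth arrest (9 and 2 of 19), antioxidant defence (7 and 9 of 27), mTOR signalling and autophagy (13 and 7 of 29, but 8 and 9 under total-count scaling), apoptosis (6 higher of 17, but 3 higher and 7 lower under total-count scaling), cholesterol synthesis (2 and 1 of 20), signalling feedback targets (5 and 9 of 27, median 0.02 and mean -0.20) and pluripotency (5 higher of 15). Under total-count scaling the medians of mTOR signalling, apoptosis, signalling feedback targets and pluripotency turned negative. Also not called were gastrulation (7 and 7 of 26), heart mesoderm (3 and 3 of 20, median 0.02 and mean -0.28), blood and endothelium (4 and 2 of 23), neural border and crest (3 and 10 of 23), endoderm and gut (3 and 2 of 15), yolk tissue (3 and 6 of 18), extracellular matrix (14 and 5 of 30), oocyte and germline (3 and 2 of 13) and leukocytes (1 higher of 14, median 0.11 with a camera direction downwards). Under total-count scaling the medians of heart mesoderm, oocyte and leukocytes turned negative. The 14 called lists became 4 with an estimated correlation.

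**Figure D4:**
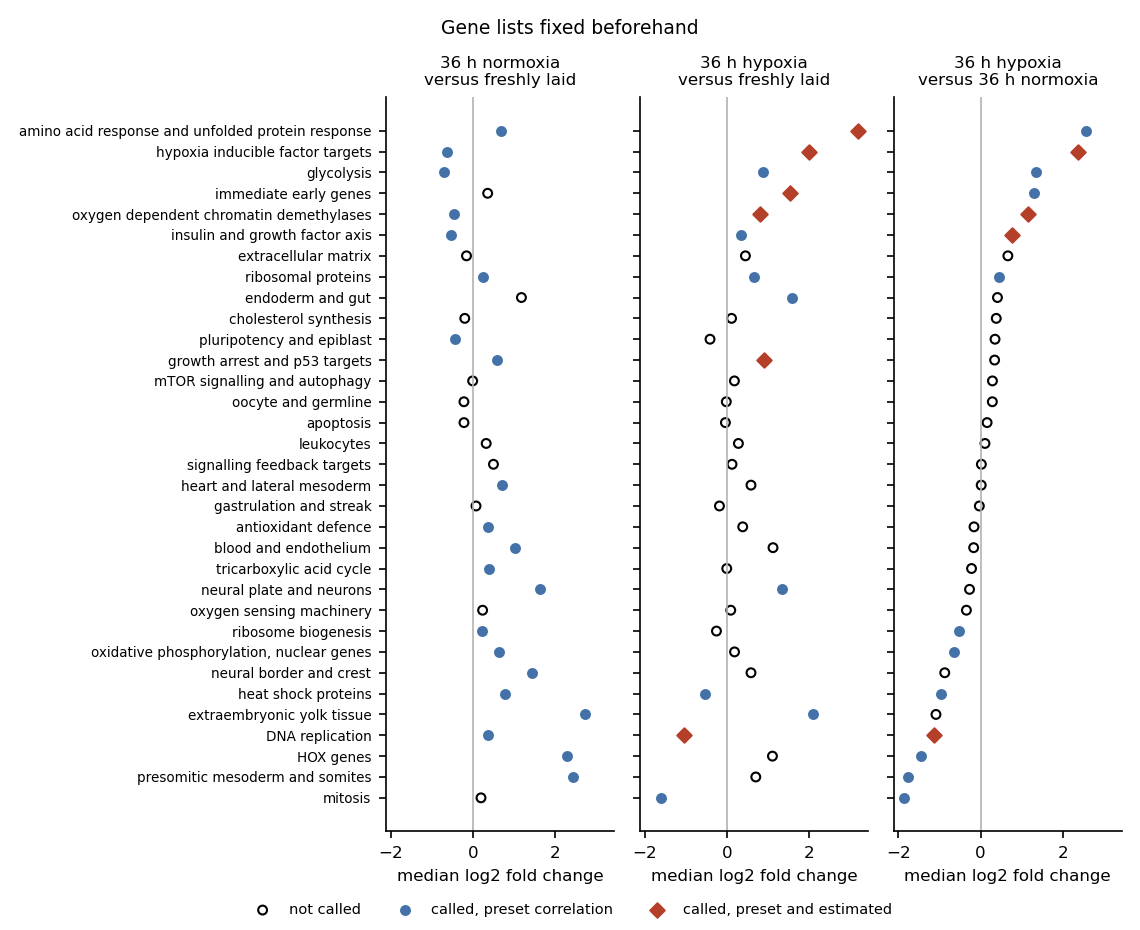
Median log2 fold change (horizontal axis) of each gene list fixed beforehand in the 3 comparisons; open points are lists that camera did not call, filled circles lists called with the preset correlation and diamonds lists called with the preset and with the estimated correlation. The numbers of called lists are 21, 14 and 14 from left to right, and those with diamonds 0, 6 and 4.

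Both 36 h groups were compared with the same 5 freshly laid libraries, and 2380 genes were called in both comparisons. Of these, 802 were higher in both groups than in freshly laid embryos, 734 lower in both, 429 higher in normoxia and lower in hypoxia, and 415 lower in normoxia and higher in hypoxia. The last 415 genes, which include EGLN3, LDHA, DDIT4 and KDM3A, were all called higher in hypoxia than in normoxia as well. The 1536 genes with the same direction compare with 1045 for independent lists of these sizes. In 20 simulations of unchanged groups against the shared libraries 0 genes were called in both comparisons, so the simulations give no scale for this count. When the freshly laid libraries were split so that each comparison had its own, the 20 splits had a median of 715.5 such genes (553 to 885). The 844 genes with opposite directions compare with 1047 for independent lists. Across genes, which are not independent replicates, the correlation of both sets of log2 fold changes was 0.348. Its median over the split controls was 0.245. The share of genes with the same sign was 56.8%. In the simulations the correlation was 0.503 (0.480 to 0.525) and the share 66.5% (65.7 to 67.3%). Both simulated values come from shared libraries without any changed gene, so they give no scale for groups that hold changes. The covariance of both sets of log2 fold changes was 0.408 against 0.0898 in the simulations, a difference of 0.318. Its median over the split controls was 0.341.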

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

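The tests of the yolk tissue and hypoxia-inducible factor patterns and the scaling test of the ribosomal protein pattern were chosen after the result was seen, and the gene length test was not.

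Across 436 groups of 5 libraries, 42 had 1 library far from the other 4 by Dixon's test at a limit of 0.71. In 11 of the 42 the other 4 libraries had 0 counts, so any count passed the limit. Without these, 31 of 425 groups remained. For independent, normally distributed values the limit would pick about 1 in 20, or 21.2. The CPM were not log transformed and the groups share the same 15 libraries. The value of 21.2 is therefore only a rough guide, and no excess can be read from 31. Of the 31, freshly laid replicate 3 stood apart in 6, freshly laid replicate 4 and normoxia replicate 5 in 4 each, and freshly laid replicate 1 in 0.

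In freshly laid replicate 3, CPM was 0.603 for ATP6V1G3 (0 to 0.173 in the other 4 libraries), 2.78 for CDKN1A (5.69 to 6.60), 15.7 for IGFBP3 (6.73 to 8.61), 76.2 for SERTM1 (6.06 to 21.4) and 22.1 for TNFAIP6 (5.31 to 7.36). F7, GCM1 and SLC51B each had 0.0603 CPM there and 0 in the other 4. Freshly laid replicate 5 had 0.413 CPM of ATP12A (0 to 0.0511), 2.20 of COL13A1 (0 to 0.307), 0.184 of TWIST1 (0 to 0.0511), and 0.0918 of CLDN2 and of HES3 against 0 elsewhere. Freshly laid replicate 4 had 0.204 CPM of ATF3 (0.628 to 0.784), 21.1 of ENO2 (7.47 to 10.7), 27.1 of NDUFB10 (40.0 to 45.0) and 0.256 of SLC17A9 (0 to 0.0603). Freshly laid replicate 2 had 0.288 CPM of INA (0 to 0.0459) and 6.79 of MMD2 (1.81 to 2.96).

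Normoxia replicate 1 had 0.386 CPM of ATOH1 (0.0346 to 0.116) and 567 of DNMT3B (286 to 360). Normoxia replicate 2 had 2.36 CPM of ABCB5 (0.0964 to 0.715), 185 of FGA (7.18 to 58.0), 17.6 of TET2 (9.50 to 11.2) and 0.0774 of LRRC74A against 0 elsewhere. Normoxia replicate 3 had 1.77 CPM of SERTM1 (1.19 to 1.33) and normoxia replicate 4 had 320 of KRT8 (200 to 231). Normoxia replicate 5 had 16.7 CPM of CDKN1A (6.61 to 8.73), 103 of NDUFB10 (67.3 to 77.2), 0.238 of NODAL (0.0346 to 0.0887) and 21.3 of ZFP36 (11.4 to 12.9).

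Hypoxia replicate 1 had 19.5 CPM of MC5R (0.331 to 1.14), 16 of SH2D1A (1.59 to 4.16) and 267 of SLC2A1 (503 to 564). Hypoxia replicate 2 had 0.0547 CPM of ATP6V1G3 and the other 4 had 0. Hypoxia replicate 3 had 0.631 CPM of SPP2 (0 to 0.109), and 0.0631 of CLDN2, MSGN1 and ZNF750 against 0 elsewhere. Hypoxia replicate 4 had 49.7 CPM of C10H15orf48 (33.2 to 36.0) and 0.124 of KRT23 against 0 elsewhere.

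The entry without a gene name held 0.249% of the counts in freshly laid replicate 3 (0.0553 to 0.101% in the other 4). Its mean share, in data outside the gene tests, was 0.230% in hypoxia and 0.114% in freshly laid embryos. The exact permutation p was 0.0873, and 0.214 adjusted over 3 comparisons, so a difference is not shown.

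Of 18 yolk tissue genes, 8 were higher in both 36 h groups than in freshly laid embryos, and 1 was lower in normoxia. The camera calls of this list were lost with an estimated correlation (adjusted p 0.317 in normoxia and 0.439 in hypoxia). After removing group means, the list members rose and fell together, with a mean pairwise correlation of 0.344. The 95th percentile of 10000 random lists matched on mean expression was 0.0532. Different amounts of attached tissue may add to the spread, but genes regulated together could exceed such random lists as well. The test does not tell these apart. All 5 normoxia libraries, and 5 hypoxia libraries, had list scores above every freshly laid library, which argues against a few libraries carrying the list scores. Tissue that grew during the 36 h and tissue taken along in dissection would both give these values, and the tables do not separate them.

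All 47 ribosomal protein genes were higher in hypoxia than in freshly laid embryos, and the list had an adjusted p of 0.355 with an estimated correlation. With total counts only, the list median was still 0.3535 on the log2 scale, which argues against scaling as the only cause. The list median of 0.6578 lay inside the range of random lists matched on gene length and expression (median 0.505, central 95% of lists 0.307 to 0.666). An effect of gene length or of expression level therefore stays open. The test cannot decide it, because only members of the ribosomal protein and oxidative phosphorylation lists were kept out of the random lists. Ribosomal protein genes outside the fixed list could be among the matched genes and carry the same rise. The random lists were matched on both, so they do not tell length from expression. Over all genes, the Spearman correlation of length with log2 fold change was -0.0933 in this comparison.

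Of 31 targets of hypoxia-inducible factors, 13 were lower in normoxia and higher in hypoxia than in freshly laid embryos. In normoxia against freshly laid 15 were not called and 2 rose, and the list had an adjusted p of 0.187 with an estimated correlation. The list median in normoxia against freshly laid was -0.6201 with total counts only, -0.6507 with the index number block, and at most -0.4957 without any 1 freshly laid library. In hypoxia against freshly laid it was 1.671 with total counts and 2.021 with the block. These values argue against scaling, 1 unusual library and the index blocks as likely sources. Whether the levels in freshly laid embryos reflect low oxygen before laying stays open, because no sample from the oviduct was analysed here.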

How the results depend on the processing

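The labels do not say what the sample numbers mark, so the libraries were not paired. A replicate block of 5 sets of 50 sample numbers, chosen after seeing the data, gave 4203, 6946 and 7730 genes for normoxia against freshly laid, hypoxia against freshly laid and hypoxia against normoxia, 19, 15 and 14 lists and an overlap of 1345. Of the calls without the block, 3932 of 5193, 6388 of 6701 and 7257 of 8123 were called again, in the same order of comparisons. Among genes of the naming rule the block left HOXA7 and NDC80 not called in the first comparison and HOXB3 in the third, and called HOXD1, NODAL and SOX3 in the second. Freshly laid and hypoxia each had 1 library in each of the 5 sets. Normoxia replicate 1 lay in set 1, replicates 2 and 3 in set 3, and replicates 4 and 5 in set 5. The 5 normoxia libraries may thus stand for fewer separate backgrounds. As a hint from the data, 13 of 15 libraries correlated best with a library of their own set. Of pairs between groups, 10 of 15 within sets had a residual correlation above 0.1 (lowest 0.0439), against 2 of 60 from different sets (highest 0.128). Called genes changed most with a test against a fold of 2, which left 716, 1064 and 2035, a stricter question by construction. An adjusted p under 0.01 left 2826 and 4458 in the first 2 comparisons, also by construction. Summing neighbouring normoxia pairs, chosen after seeing the data, left 2987 genes in the first and an overlap of 948, with fewer libraries by construction. With an estimated correlation 0, 6 and 4 lists remained of 21, 14 and 14, and the cause was not tested. The overlap was 1536 with all freshly laid libraries, and the median with split controls was 715.5, from fits that also have fewer libraries. Leaving out 1 library, for lists and overlap chosen after seeing the data, gave 4076 to 5110, 5840 to 6574 and 7382 to 8103 genes, 18 to 22, 14 to 16 and 13 to 15 lists, and an overlap of 1220 to 1596. The index number block, also chosen after seeing the data, gave 4580, 6670 and 7467 genes. Total counts only kept the numbers of called genes within 1.5 times but moved their split by more, to 2088 higher and 5259 lower in the second comparison and 2674 higher in the third. Every other setting run kept the counts of genes within 1.5 times. Lists were run only with the estimated correlation, median-ratio factors, summed pairs, both blocks and left-out libraries, and only the first moved them over 1.5 times. No named gene reversed its direction with a call in the settings run for it. Outside the replicate block, changed calls of the genes discussed are given beside them, and the cause was not tested. Depth limits genes near the floor of 3 counts per group, for which only lower limits or wide intervals are given.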

Other observations

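The programme tests below were chosen after the result was seen, and the sample number test and the splits were not.

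Shares of the normoxia rise reached in hypoxia were computed for 7 lists of developmental programmes, and only those of the neural and yolk lists were tested against that of the somite list. Taking the rise from freshly laid embryos to normoxia as 100%, hypoxia libraries reached 27.8 ± 11.1% for the somite list, 36.6 ± 10.4% for neural border and crest, 39.3 ± 28.2% for HOX genes, 43.1 ± 70.1% for heart mesoderm, 66.1 ± 37.9% for yolk tissue and 94.1 ± 20.1% for neural plate and neurons (SD, n = 5). Endoderm and gut, a list not called in normoxia against freshly laid embryos (camera adjusted p = 0.0587), reached 172 ± 49.1%. Scores in hypoxia differed from freshly laid embryos for 5 lists (adjusted exact permutation p 0.0111 each) and not for HOX genes and heart mesoderm (0.12 and 0.325). The 5 include the somite and the border and crest lists, which camera did not call there (camera adjusted p = 0.151 each). Hypoxia scores differed from normoxia for the somite, border and crest, and HOX lists (adjusted exact permutation p 0.0185 each). For the other 4 they did not (0.0555 for endoderm and gut to 0.651 for the neural list). Camera did not call border and crest against normoxia either (camera adjusted p = 0.0614). The permutation test compares library scores of a list, while camera sets its genes against all other genes. The neural list exceeded the somite list by 66.3 ± 19.9 percentage points in the hypoxia libraries. This difference was permuted between hypoxia and normoxia libraries, and the normoxia libraries average no difference by construction. The exact permutation p, adjusted over the neural and yolk lists, was 0.0159, where the smallest possible unadjusted p is 0.00794. The freshly laid and normoxia means that define the shares stayed fixed, so their error enters neither the SD nor the p. For the neural list the freshly laid score was 0.485 ± 0.605 and the normoxia mean 1.963. The yolk list exceeded the somite list by 38.3 ± 28.9 points, with an adjusted p of 0.214 in the same exact permutation test. A p of this size does not show that both shares are equal. These scores come from whole embryos, so changes within cells and changes in the share of a tissue remain mixed.

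Embryos in hypoxia held 28 of 28 stress response genes above freshly laid levels, while in normoxia 12 of these genes were higher, 2 lower and 14 not called. Of 35 replication genes, 11 were higher in normoxia and lower in hypoxia than in freshly laid embryos, and of 18 chromatin demethylases 8 were lower in normoxia and higher in hypoxia.

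Libraries of 1 group differed from each other, and eggs with close sample numbers might share a background such as a clutch. Over 105 pairs, the Mantel correlation of sample number difference and residual correlation was -0.322, with a one-sided permutation p of 0.00267. The 2 neighbouring normoxia pairs had residual correlations of -0.0135 and 0.205, against -0.463 to -0.163 in the other 8 normoxia pairs. A shared clutch, a shared day and a shared handling batch would all give this, so the libraries of a group may be less independent than the tests assume.

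Groups were also redrawn at random from the same libraries, with 100 splits of each comparison including the real one. For called genes, 1 split, the real one, reached the real values of 5193, 6701 and 8123, and the highest others were 726, 1101 and 537, so a random division of the libraries can be excluded as their source. For called lists in normoxia against freshly laid, the real 21 was reached by 1 split, with 20 as the highest other. In hypoxia against freshly laid, 14 of 100 splits gave at least the real 14 lists (highest other 19), and in hypoxia against normoxia 23 of 100 did (highest other 17). Redrawn splits can keep part of the real group difference. In addition, most redrawn splits of hypoxia against normoxia had 0 called genes, and these splits still called 3 to 17 lists. Camera with the preset correlation can thus call many lists where no gene is called. The splits therefore cannot test the list counts in either direction, and chance is neither excluded nor shown for any of them. Oxidative phosphorylation genes had a list median of 0.64 in normoxia against freshly laid, above the upper end of 0.43 of the central 95% of lists matched on gene length and expression, and -0.66 in hypoxia against normoxia, below the lower end of -0.48. In hypoxia against freshly laid the median of 0.19 lay inside the matched range of -0.17 to 0.39. With an estimated correlation the list had an adjusted p of 0.276 in normoxia against freshly laid and 0.571 in hypoxia against normoxia.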
